A study of Mus musculus with 10 samples.

How the data were processed

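Gene expression was measured in kidneys of male C57BL/6 mice aged 30 months with 10 Affymetrix Mouse Genome 430 2.0 arrays, 1 mouse per array. The labels put 5 mice in a control diet group and 5 in a long-term calorie restriction group. The degree and duration of the restriction, the time of day and the feeding state at tissue collection are not given in the sources used here. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from 5 ug of it.

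The deposited values are the authors' MAS5 signals, an intensity on a linear scale for each probe set, made in Affymetrix Expression Console per the submitters' processing notes; the versions are not given there. MAS5 subtracts mismatch probe signal and scales each array. In the deposited intensity values the mean of each array without the lowest and highest 2% of probe sets was 499.8 on every array, so arrays were scaled to a common mean, and no quantile or similar normalization was visible. Such a scaling leaves differences between arrays that change with brightness, and it levels a trimmed mean, not the total of the signal. The mean over all probe sets stayed unequal, at 755 to 768 on control and 786 to 831 on calorie-restricted arrays. Background of the single arrays and detection calls were not used here. The number of arrays, 5 per group, limits the precision.

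The table holds 45101 probe sets, 64 of them Affymetrix controls. Genes were named from the platform annotation: 34958 probe sets had 1 gene symbol, 932 had several and were left unnamed, and 9211 had none. The gene IDs of 34754 probe sets were found in a RefSeq gene table, which changed 0 symbols. Probe sets whose names end in s_at or x_at can bind transcripts of related genes. Values of near-identical paralogs (the Nat8 family, immunoglobulin genes) are therefore uncertain as to the single gene.

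Signals below 1 were set to 1 (922 values in the whole table and 0 among the tested probe sets) and log2 was taken. Control probe sets were left out, and probe sets were tested if their mean log2 signal over all 10 arrays was at or above the median of all probe sets, log2 6.81, which left 22519 probe sets and 12196 named genes. Calorie restricted minus control was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 2-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 on the adjusted p. All differences are log2 values, calorie restricted minus control, with the standard error from limma and n = 5 per group. A gene's value is that of its probe set with the highest mean signal. The limma tests of probe sets rest on 1 mouse per array, so their p-values measure the spread between these mice.

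The gene lists, the limma, camera and fry tests, the test of RNA quality between the diets, the rule for named genes and the alternatives not named below as added were fixed before the data were examined. Of 46 lists of genes (metabolic pathways, stress and immune genes, and markers of kidney and other cell types), the 44 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, 2-sided, adjusted over the lists. Camera compares the members of a list with all other genes. Its p-values at the preset correlation rest on the spread between genes and on that assumed value. They do not measure the spread between mice. Camera with an estimated correlation, fry (which asks whether members move on balance one way, without comparing them with other genes) and an exact permutation test of the per-array means of a list were run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. Named genes were, first, the 12 largest rises and 12 largest falls among genes past the threshold whose 5 calorie-restricted values all lay on one side of all 5 control values, and second, in each list, up to 4 members with the smallest p among those past the threshold, or up to 2 given as values where none passed.

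RNA quality was followed with the log2 ratio of the 3' to the 5' control probe sets of Gapdh and Actb on each array, tested between the diets with a 2-sided exact permutation test. After the data were seen, these settings were added: that ratio as a covariate, calorie-restricted replicates 4 and 5 against all controls, replicates 4 and 5 of each group alone, and the covariate or these replicates together with quantile normalization. The exact permutation test of the per-array means of lists was also added then, as were the comparisons of replicates 1 to 3 with 4 and 5 and the tests of dilution and of T cell markers. The other settings tried were no filter and a stricter one (top 30% by mean signal), quantile normalization, median centring, log2(signal + 50), eBayes without trend and with a robust fit, array weights, other thresholds, the replicate number as a block, each array left out in turn, and the mean of a gene's probe sets. For lists, counts and ranges over 24 or 25 alternatives rest on camera at the preset correlation. They leave out the estimated correlation, fry and the exact permutation test.

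The fit was tested on simulated data with the variances of these arrays. For the comparison of calorie restricted with control over 22519 probe sets, it called 14 of 65 probe sets moved by a log2 step of 0.5, 48 of 65 moved by 1 and 55 of 59 moved by 2, with 9 false calls among 126. A simulated shift of the respiratory chain list by 0.2 was called, with 0 of 42 lists that share no member called beside it. The simulated probe sets varied independently of each other. The simulation therefore cannot show how many lists camera calls by chance where genes move together.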

Results

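Kidney transcripts of 5 mice fed a control diet and 5 mice under long-term calorie restriction were compared at 30 months of age, to find which genes respond to lasting calorie restriction in an old kidney. Each array gave a MAS5 signal for 45101 probe sets, with a median signal between 115 and 136 per array. Spearman's rho across all probe sets was 0.926 to 0.951 between arrays of a group and 0.922 to 0.950 between arrays of different groups, and no 2 arrays were identical.

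The 3' to 5' signal ratio of Gapdh and Actb, which rises when RNA is shorter or labelling is less complete, was not equal between the diets. Its mean log2 value was 1.05 ± 0.26 in control and 1.67 ± 0.46 in calorie-restricted kidney (SD, n = 5, exact permutation p = 0.0476). Calorie-restricted replicates 1, 2 and 3 stood at 2.21, 2.01 and 1.75, above all controls, while replicates 4 and 5 stood at 1.24 and 1.16, within the control range of 0.76 to 1.39. Without any 1 of replicates 1, 2 and 3 of either group the exact permutation p was 0.0714 to 0.0794. Replicates 4 and 5 of the 2 groups had like ratios, with means of 1.32 in control and 1.20 in calorie restriction. Values of these 4 arrays alone are therefore given beside most groups below. Controls 4 and 5 had the highest ratios of the controls, 1.39 and 1.25 against 0.76 to 0.94. The same 2 arrays had the highest or lowest means of the controls for many gene lists below, so these values also depend on that choice of controls. The ratio of Pcx, not part of this mean, was 5.11 in controls 4 and 5 and 4.81 in calorie-restricted replicates 4 and 5.

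**Figure D1:**
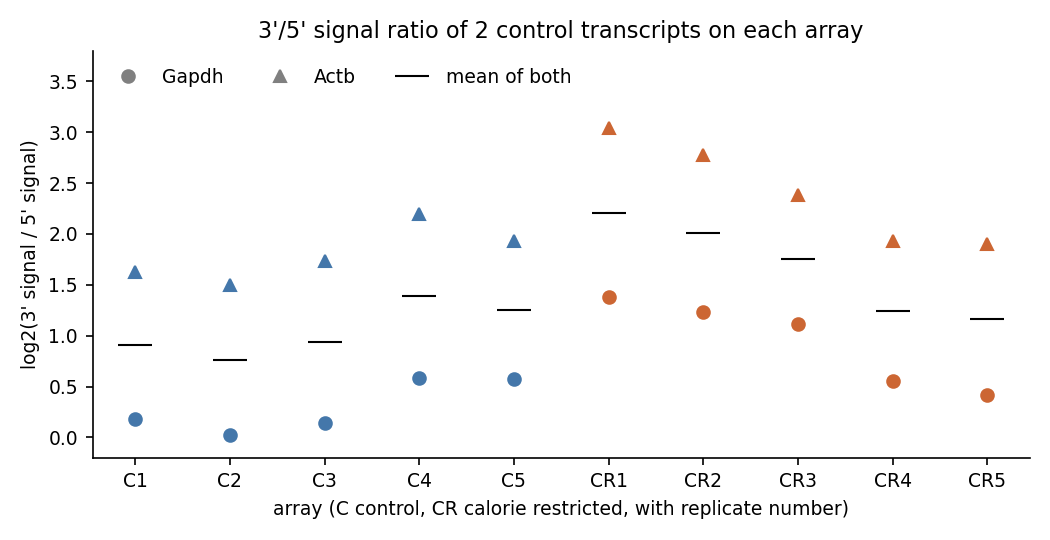
Log2 ratio of 3' to 5' signal of Gapdh (circles) and Actb (triangles) on each of the 10 arrays, with their mean as a bar; control arrays in blue and calorie-restricted arrays in orange. The means of calorie-restricted replicates 1 to 3, from 1.75 to 2.21, lie above the highest control at 1.39.

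Among genes past the threshold whose calorie-restricted and control values did not overlap, each taken by its brightest probe set, the 12 largest rises included 2 members of the N-acetyltransferase 8 family, the mitochondrial adenylate kinase Ak4 and the retinol carrier Rbp4. Nat8f1 rose from 9989 ± 2452 to 19968 ± 880.3 signal units (SD, n = 5), a log2 difference of 1.03 ± 0.13, and Nat8f5 from 1682 ± 510.3 to 3056 ± 361, a difference of 0.91 ± 0.18. The other Nat8f1 probe set tested moved the other way without passing the threshold. Ak4 rose from 7050.1 ± 1155 to 13375 ± 404, a difference of 0.94 ± 0.10, and Rbp4 by 1.02 ± 0.25 on the log2 scale. Other rises were those of the transcription factor Nfic (1.20 ± 0.25), the T cell kinase Zap70 (1.03 ± 0.26), and the cytoskeletal protein talin 2, Tln2 (0.97 ± 0.20). Smaller ones were those of the histone mRNA processing factor Lsm11 (0.92 ± 0.25), Susd2 (0.89 ± 0.15), the small heat shock protein Hspb7 (0.87 ± 0.22), the solute carrier Slc16a9 (0.86 ± 0.16) and the phosphatase 2A activator Ptpa (0.84 ± 0.17). Lsm11 and Hspb7 had mean control signals of 107.9 and 95.3, below the median signal of every array, so the sizes of their rises are uncertain. In replicates 4 and 5 alone the differences of Nfic, Zap70 and Ptpa were 0.31, 0.42 and 0.28, while those of Nat8f1, Ak4, Rbp4 and Nat8f5 were 1.34, 0.97, 1.40 and 1.23.

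Among the same kind of genes the deepest falls were those of Slpi, a secreted protease inhibitor, and of Iglv1, an immunoglobulin light chain segment. Slpi fell from 3979 ± 3407 to 491 ± 194 signal units (SD, n = 5), a log2 difference of -2.70 ± 0.46, and Iglv1 from 1722 ± 942 to 438 ± 452, a difference of -2.70 ± 0.69. The core clock gene Arntl fell from 462 ± 165 to 144 ± 72.6, a difference of -1.85 ± 0.42. Further falls were those of the small GTPase Gem (-1.55 ± 0.25), Rab3gap2 (-1.38 ± 0.32), the cytokine Clcf1 (-1.35 ± 0.26) and the carboxypeptidase Folh1 (-1.35 ± 0.24). Next in size came Clca3a1 (-1.29 ± 0.24), the B cell coactivator Pou2af1 (-1.23 ± 0.30), carboxypeptidase E, Cpe (-1.19 ± 0.18), the calcium channel subunit Cacna2d1 (-1.18 ± 0.23) and the matrix proteoglycan lumican, Lum (-1.17 ± 0.24). Gem and Cacna2d1 had mean calorie-restricted signals of 80.9 and 85.1, below the median signal of every array, so the sizes of their falls are uncertain. Adjusted p over these 24 genes ran from 0.00337 to 0.0437. In replicates 4 and 5 alone Slpi differed by -3.95, Gem by -2.23, Iglv1 by -1.86 and Folh1 by -0.90.

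**Figure D2:**
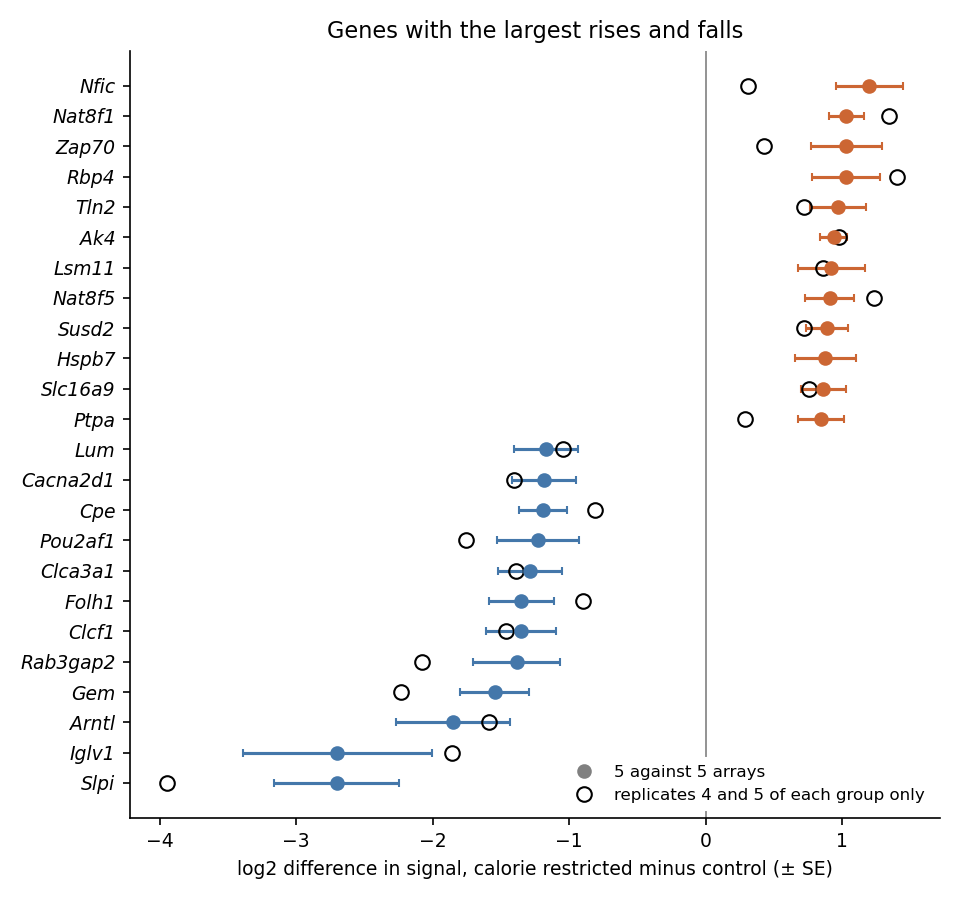
Log2 difference in signal, calorie restricted minus control, with its standard error, for the 12 largest rises (orange) and the 12 largest falls (blue) among separated genes past the threshold, 5 arrays per group. Open circles give the difference in replicates 4 and 5 of each group alone, which for Nfic is 0.31 against 1.20 and for Nat8f1 1.34 against 1.03; Hspb7 was too dim to be tested there.

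Over all genes, 1371 of 22519 probe sets passed the adjusted p threshold of 0.05 in limma, 659 of them higher and 712 lower in calorie restriction. They stood for 1050 genes, 464 higher, 582 lower and 4 with probe sets called both ways. Of 655 other probe sets of 395 genes called by their brightest probe set, 75.1% moved in the same direction. For genes whose brightest probe set was not called, which include some of the 1050, this was 57.6%. The 2 diets did not overlap in 7.12% of tested probe sets, where chance gives 0.794%. With the 3' to 5' ratio as a covariate 9 probe sets passed, with calorie-restricted replicates 4 and 5 against all controls 2, and with replicates 4 and 5 of each group alone 207. Of 92 genes named here that passed, 3 still passed with the covariate, Nat8f1, Ak4 and Gem, 0 with those 2 calorie-restricted arrays and 18 of 91 with replicates 4 and 5 alone. With 1 array left out 26 (without control replicate 2) to 90 (without calorie-restricted replicate 5) of the 92 still passed, and 30, 36, 44, 48, 60 and 65 without calorie-restricted replicate 2, 1 or 3 or control replicate 4, 3 or 5. Without control replicate 2, 3, 4 or 5 the count was 125, 516, 419 and 781, and without calorie-restricted replicate 1, 2, 3, 4 or 5 it was 251, 179, 331, 2103 and 2485.

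Markers of the proximal tubule, the segment that reabsorbs most of the filtrate, were higher in calorie-restricted kidney. Of 25 measured markers 15 rose over all genes and 17 rose adjusted over the list alone, where 1 fell. Examples were the kidney androgen-regulated protein Kap (0.74 ± 0.11), the acyl-CoA synthetase Acsm2 (0.69 ± 0.11), Ttc36 (0.50 ± 0.066) and the gluconeogenic enzyme Fbp1 (0.37 ± 0.066). After quantile normalization these were 0.40, 0.41, 0.26 and 0.018, and Acsm2 and Fbp1 no longer passed. The median of the list was 0.38 (camera adjusted p = 3.90e-10, adjusted p = 0.370 with an estimated correlation). Its mean was higher on 5 of 5 calorie-restricted arrays than on any control array (exact permutation p = 0.00794). That is the smallest p 5 against 5 can give, and 0.116 after adjustment over the lists by the exact permutation test. The median was 0.35 in replicates 4 and 5 alone and 0.10 after quantile normalization (adjusted p = 0.00723, range over 25 alternatives 5.78e-12 to 0.00723). Controls 4 and 5 had the lowest list means of the controls (-0.20 and 0.015 against 0.036 to 0.086).

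Podocyte markers moved the other way. Of 12 measured markers 3 fell over all genes and 5 adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.000847, adjusted p = 0.370 with an estimated correlation). They were nephronectin, Npnt (-0.91 ± 0.15), the transcription factor Wt1 (-0.71 ± 0.18) and the slit diaphragm adaptor Cd2ap (-0.44 ± 0.12), the 3 that passed over all genes. Of the other probe sets, 2 of 3 for Npnt and 1 of 2 for Cd2ap moved the other way without passing the threshold. The median was -0.58 in replicates 4 and 5 alone, where controls 4 and 5 had the highest list means of the controls (0.25 and 0.19 against -0.34 to -0.053). Markers of fibroblasts, mesangial cells and smooth muscle had a median of -0.25, with 2 of 15 members lower over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0265, adjusted p = 0.506 with an estimated correlation). The platelet-derived growth factor receptor Pdgfra fell by 0.95 on the log2 scale, and Lum is also in this list. The stromal call was lost without control replicate 5 (median -0.11, adjusted p = 0.143), without calorie-restricted replicate 4 (-0.11, 0.115), with array weights (0.0929) and with the stricter filter (0.0668). The adjusted p ranged from 1.36e-06 to 0.143 over 25 alternatives, and the stromal median in replicates 4 and 5 alone was -0.43. Controls 4 and 5 were the highest controls here too (0.091 and 0.34 against -0.18 to -0.085). Markers of the thick limb and distal tubule (median 0.048, 0 of 16 past the threshold, camera adjusted p = 0.813) did not pass the list test. Nor did those of the collecting duct (0.038, 2 of 19 higher, 0.185) and the endothelium (-0.11, 0 of 18, 0.288). The thick limb protein Umod differed by 0.29 ± 0.084 at the authors' scaling and -0.061 after quantile normalization, and the endothelial Pecam1 by -0.60 ± 0.19, both short of the threshold. Umod differed by 0.13 and Pecam1 by -0.015 in replicates 4 and 5 alone, and with the 3' to 5' covariate by 0.15 and -0.10. Without calorie-restricted replicate 5 both passed (0.33 and -0.76). The water channel Aqp6 of the collecting duct rose (0.77 ± 0.14, 0.34 in replicates 4 and 5 alone).

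**Figure D3:**
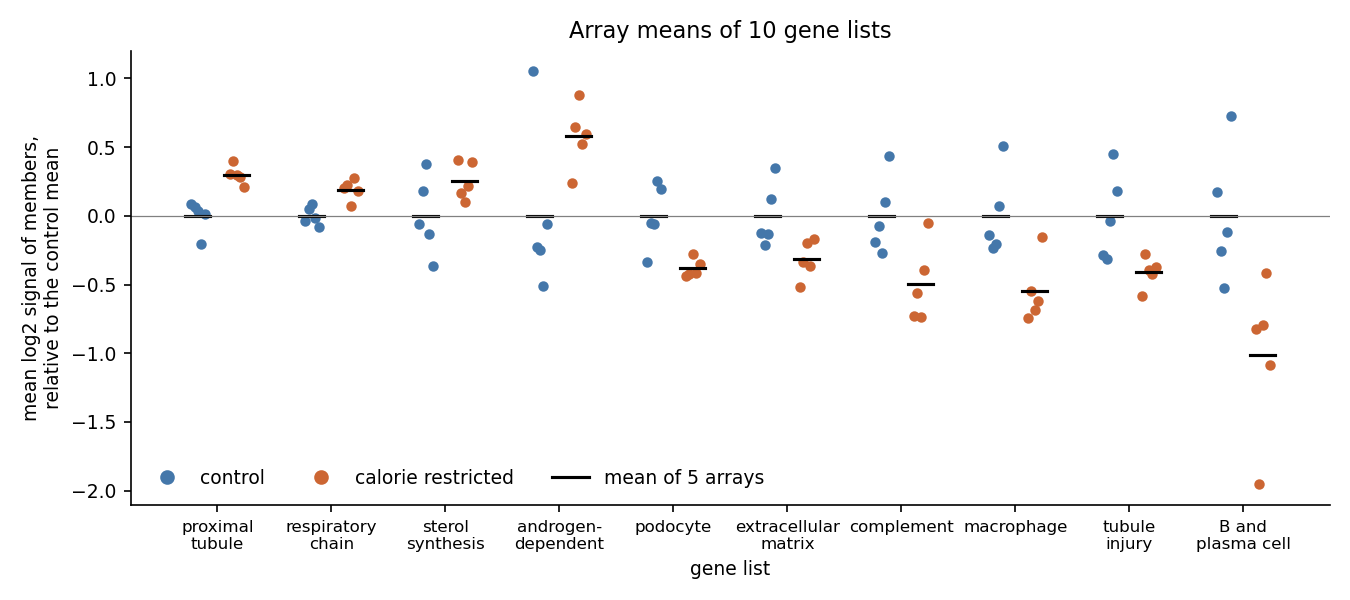
Mean log2 signal of the measured members of 10 gene lists on each array, relative to the mean of the 5 control arrays; points are arrays (control blue, calorie restricted orange) and bars the mean of 5 arrays. The 5 calorie-restricted arrays lie above all controls for the proximal tubule, with a mean of 0.30 ± 0.067 (SD), and control replicate 1 stands at 1.05 for the androgen-dependent genes.

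Macrophage, complement, matrix and tubule injury genes were lower in calorie-restricted kidney. Among macrophage and monocyte markers 5 of 19 fell over all genes and 12 adjusted over the list alone, with a median of -0.55 (camera adjusted p = 1.36e-06, adjusted p = 0.370 with an estimated correlation). They included the pore-forming protein Mpeg1 (-1.02 ± 0.17), the protease Ctss (-0.63 ± 0.13), the lipopolysaccharide co-receptor Cd14 (-0.73 ± 0.16) and the mannose receptor Mrc1 (-0.87 ± 0.22). Complement genes had a median of -0.49, with 2 of 10 lower over all genes, C1s1 (-1.11 ± 0.25) and the receptor C3ar1 (-0.86 ± 0.21). The number that fell was 7 adjusted over the list alone (camera adjusted p = 0.00290, adjusted p = 0.456 with an estimated correlation). The complement call was lost with calorie-restricted replicates 4 and 5 against all controls (median -0.30, adjusted p = 0.0740, range 5.20e-05 to 0.0740). In replicates 4 and 5 alone the medians were -0.67 and -0.55. Controls 4 and 5 had the highest means of the controls for macrophage (0.069 and 0.51 against -0.23 to -0.14) and complement genes (0.10 and 0.44 against -0.27 to -0.075).

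Extracellular matrix genes fell in 5 of 33 cases over all genes and in 12 adjusted over the list alone (median -0.26, camera adjusted p = 0.000106, adjusted p = 0.456 with an estimated correlation). Among them were the collagen cross-linking enzymes Lox (-0.93 ± 0.20) and Loxl1 (-0.56 ± 0.12) and thrombospondin 1, Thbs1 (-0.94 ± 0.22, -0.31 in replicates 4 and 5 alone). Tubule injury and repair genes fell in 4 of 18 cases over all genes. Adjusted over the list alone 7 fell and 1 rose (median -0.47, camera adjusted p = 0.00468, adjusted p = 0.492 with an estimated correlation). The 4 that passed over all genes were the adhesion molecule Vcam1 (-0.92 ± 0.20), the chemokine Ccl2 (-1.17 ± 0.26), the cytokine Il34 (-0.73 ± 0.19) and the receptor Tnfrsf12a (-0.97 ± 0.27). Ccl2 had a mean calorie-restricted signal of 100.4, below the median signal of every array, so the size of its fall is uncertain. With the stricter filter the injury list had an adjusted p of 0.0678 (range 6.66e-11 to 0.0678). Immediate early genes had a median of -0.29 with 1 of 20 lower over all genes, Klf6 (-0.77 ± 0.16). Adjusted over the list alone 8 fell and 1 rose (camera adjusted p = 0.00681, adjusted p = 0.460 with an estimated correlation). Without control replicate 5 that call was lost (median -0.23, adjusted p = 0.0934, range 5.26e-07 to 0.0934). Glucocorticoid- and FoxO-responsive genes had a median of -0.36, with 1 of 21 lower over all genes, the sestrin Sesn1 (-0.54 ± 0.13). The number that fell was 7 adjusted over the list alone (camera adjusted p = 0.0228, adjusted p = 0.506 with an estimated correlation). That call was lost without control replicate 5 (median -0.082, 0.126) and without calorie-restricted replicate 5 (-0.22, 0.107), and the median was -0.21 without control replicate 4. The adjusted p ranged from 1.29e-10 to 0.126 over 25 alternatives. The medians of the 4 lists in replicates 4 and 5 alone were -0.49, -0.78, -0.52 and -0.50. In each of the 4 lists controls 4 and 5 had the highest means of the controls. These were 0.12 and 0.35 against -0.21 to -0.12 for matrix and 0.45 and 0.18 against -0.31 to -0.037 for injury genes. They were 0.21 and 0.30 against -0.24 to -0.11 for immediate early and 0.15 and 0.38 against -0.33 to -0.068 for glucocorticoid and FoxO genes.

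Of 8 tested lists of immune genes, immune cells and other tissue 4 passed, all lower. They were the macrophage list and the complement list above, whose genes kidney cells can also express, and 2 more. B cell and plasma cell markers fell in 2 of 11 cases over all genes, Iglv1 and Pou2af1. Adjusted over the list alone 6 fell (median -1.0, camera adjusted p = 0.00107, adjusted p = 0.370 with an estimated correlation, -0.86 in replicates 4 and 5 alone). Adipocyte markers, which can come from fat around the kidney, had a median of -0.30, with 2 of 11 lower over all genes, the fatty acid binding protein Fabp4 (-0.77 ± 0.14) and the lipid droplet protein Cidea (-1.10 ± 0.29). The number that fell was 4 adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.456 with an estimated correlation). The adipocyte list mean was lower on 5 of 5 calorie-restricted arrays than on any control array (exact permutation p = 0.00794, the smallest 5 against 5 can give). The call was lost without control replicate 1 (median -0.24, adjusted p = 0.0833), with the 3' to 5' covariate (-0.29, 0.11) and in replicates 4 and 5 alone (median -0.36, 0.0735). The adjusted p ranged from 0.00290 to 0.11 over 25 alternatives. Neutrophil markers (median -0.58, 0 of 6 past the threshold, camera adjusted p = 0.0755) and T cell markers (0.041, 0 of 8, 0.852) did not pass. The same held for MHC class II genes (0.027, 0 of 8, 0.865) and for liver markers (0.13, 1 higher and 1 lower of 11, 0.774). The neutrophil proteins S100a8 (-1.70 ± 0.60) and S100a9 (-1.69 ± 0.57) did not pass (adjusted p = 0.0959 and 0.0855), but did without control replicate 1 (-2.31 and -2.22), and S100a9 without calorie-restricted replicate 5 (-2.03). Adrenal (median 0.27) and red cell markers (0.58) had 4 measured members each, too few for the list test. All 4 of each were above 0, and adjusted over the list alone 1 adrenal and 3 red cell markers rose. The red cell mean was 0.24 to 0.79 on calorie-restricted arrays, above all controls (at most 0.18). Of the red cell markers Slc4a1, which collecting duct cells also express, rose over all genes (0.64 ± 0.17, 0.20 in replicates 4 and 5 alone).

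Cholesterol synthesis genes were higher in calorie-restricted kidney by camera at the preset correlation. Their array means lay above all controls on 2 of 5 calorie-restricted arrays (exact permutation p = 0.111, unadjusted). Of 18 members 4 rose over all genes and 5 adjusted over the list alone (median 0.22, camera adjusted p = 0.00681, adjusted p = 0.456 with an estimated correlation). The 4 that passed over all genes were Hmgcs1 (0.68 ± 0.11), lanosterol synthase, Lss (0.70 ± 0.16), mevalonate kinase, Mvk (1.0 ± 0.23), and Dhcr7 (0.68 ± 0.17). The median was 0.15 without calorie-restricted replicate 5, and the call was lost without control replicate 5 (median 0.13, adjusted p = 0.0934) and for the mean of a gene's probe sets (0.0536). The adjusted p ranged from 1.12e-08 to 0.0934 over 25 alternatives, and the median in replicates 4 and 5 alone was 0.48. Controls 4 and 5 had the lowest sterol list means of the controls (-0.13 and -0.37 against -0.062 to 0.38). Fatty acid synthesis genes rose in 2 of 16 cases, both over all genes and adjusted over the list alone. They were the acetyl-CoA synthetase Acss2 (0.75 ± 0.16) and the regulator Srebf1 (0.55 ± 0.15) (median 0.24, camera adjusted p = 0.00597, adjusted p = 0.370 with an estimated correlation). That call was lost with the 3' to 5' covariate (0.0766), with calorie-restricted replicates 4 and 5 against all controls (0.0740) and for the mean of a gene's probe sets (0.0791). The adjusted p ranged from 0.000847 to 0.0791 over 25 alternatives, and the median in replicates 4 and 5 alone was 0.23. The same 2 controls were lowest for this list (-0.014 and -0.16 against 0.021 to 0.12).

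Nuclear genes of the respiratory chain and ATP synthase rose in 23 of 55 cases over all genes and 26 adjusted over the list alone, among them Uqcrc2 (0.47 ± 0.077), Ndufb7 (0.49 ± 0.085), Cox6b1 (0.42 ± 0.071) and Atp5g3 (0.40 ± 0.072). The median was 0.18 (camera adjusted p = 8.33e-12, adjusted p = 0.370 with an estimated correlation), and 0.29 in replicates 4 and 5 alone. Bright probe sets were higher in calorie restriction on median. The median difference was 0.28 for 307 probe sets above a mean log2 signal of 14 and -0.052 for 4453 between 9 and 10. After quantile normalization, which levels this trend, the respiratory chain median was 0.000188 (adjusted p = 0.839, range 9.04e-21 to 0.839). The call held in 24 of 25 alternatives with camera at the preset correlation. Among these 24 were quantile normalization with the 3' to 5' covariate (median 0.056, adjusted p = 0.00256) and on replicates 4 and 5 alone (0.10, 3.77e-05). It did not hold in the exact permutation test of array means (adjusted p = 0.116). Ribosomal protein genes, 6 of 29 higher over all genes (adjusted over the list alone 8 higher and 1 lower), moved with the scaling. Their median was 0.13 at the authors' scaling (camera adjusted p = 0.000710, adjusted p = 0.456 with an estimated correlation) and 0.10 in replicates 4 and 5 alone. It was -0.070, in the other direction, after quantile normalization (adjusted p = 0.0170, range 2.89e-05 to 0.0315). Rpl38 was 0.33 ± 0.074 at the authors' scaling and -0.017 after quantile normalization. The same normalization ended the calls of 4 more lists that were higher at the authors' scaling, those of gluconeogenesis, NRF2, hypoxia and xenobiotic genes. Gluconeogenesis genes rose in 4 of 11 cases, over all genes and adjusted over the list alone, with Fbp1 and G6pc3 (0.48 ± 0.11) among them (median 0.10, camera adjusted p = 0.0480, adjusted p = 0.370 with an estimated correlation, 0.839 after quantile normalization). That call held in 10 of 25 alternatives (range 0.00180 to 0.839). It was lost without control replicate 1, 4 or 5 (adjusted p = 0.0846, 0.137 and 0.0870) or calorie-restricted replicate 1, 4 or 5 (0.0592, 0.103 and 0.0766). Its median in replicates 4 and 5 alone was 0.18. NRF2 targets and glutathione genes rose in 7 of 24 cases over all genes and 9 adjusted over the list alone. Gpx1 (0.35 ± 0.070) and Gstp1 (0.47 ± 0.10) were among them. The list had a median of 0.16, and 0.25 in replicates 4 and 5 alone (camera adjusted p = 0.00432, adjusted p = 0.370 with an estimated correlation, 0.274 after quantile normalization, range 8.03e-06 to 0.274). Hypoxia-inducible and glycolysis genes rose in 2 of 19 cases over all genes, Pgk1 (0.53 ± 0.081) and the carbonic anhydrase Car9 (0.94 ± 0.21). The number that rose was 7 adjusted over the list alone (median 0.14, camera adjusted p = 0.0233, adjusted p = 0.370 with an estimated correlation, 0.380 after quantile normalization). In replicates 4 and 5 alone the hypoxia median was -0.044 (adjusted p = 0.782, range 0.0124 to 0.999). The call was also lost with the 3' to 5' covariate (0.290) and without control replicate 1 (0.0717) or calorie-restricted replicate 1 or 2 (0.0543 and 0.0638).

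**Figure D4:**
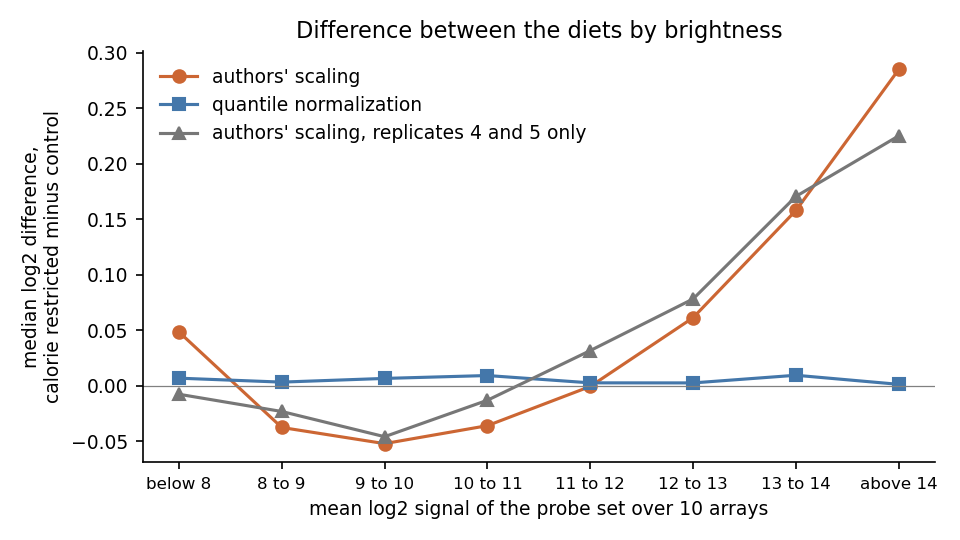
Median log2 difference, calorie restricted minus control, of tested probe sets by their mean log2 signal, at the authors' scaling (orange circles), after quantile normalization (blue squares) and at the authors' scaling in replicates 4 and 5 alone (grey triangles). Above a log2 signal of 14 the 3 medians are 0.28, 0.0011 and 0.22.

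Kidney genes that depend on androgens or are higher in males had a median of 0.60, and 4 of 15 rose while 1 fell over all genes. Adjusted over the list alone 8 rose and 2 fell (camera adjusted p = 0.00259, adjusted p = 0.456 with an estimated correlation, median 0.59 in replicates 4 and 5 alone). The rises were those of Kap, the alcohol dehydrogenase Adh1 (0.60 ± 0.12) and the cytochromes P450 Cyp4b1 (0.69 ± 0.14) and Cyp2e1 (0.41 ± 0.11). After quantile normalization they were 0.40, 0.38, 0.39 and 0.17, and of these only Kap still passed. The list median was then 0.39, and the list still passed (camera adjusted p = 0.0231). The fall was that of Hsd11b1 (-0.49 ± 0.13), an enzyme of glucocorticoid activation that was named after its values were seen. It differed by -0.055 in replicates 4 and 5 alone. Organic anion, cation and drug transporters rose in 3 of 18 cases over all genes, Slc22a6 (0.60 ± 0.13), the urate transporter Slc22a12 (0.69 ± 0.16) and Slc22a2 (0.71 ± 0.17). The number that rose was 4 adjusted over the list alone (median 0.19, 0.28 in replicates 4 and 5 alone, camera adjusted p = 0.00290, adjusted p = 0.370 with an estimated correlation). After quantile normalization the transporter median was 0.10 (camera adjusted p = 0.0349). Xenobiotic metabolism genes went both ways, 8 of 23 higher and 3 lower over all genes (11 and 3 adjusted over the list alone), with Nat8 higher (0.63 ± 0.12) and Cyp1b1 lower (-0.82 ± 0.14). Their median was 0.26 (camera adjusted p = 0.00681, adjusted p = 0.370 with an estimated correlation, 0.181 after quantile normalization, range 3.14e-05 to 0.181) and 0.40 in replicates 4 and 5 alone. For the androgen list control replicate 1, at 1.05, lay above every calorie-restricted array (0.24 to 0.88), and the exact permutation p between the diets was 0.0873. This array stood above the other controls not in the androgen list alone but also for transporters (0.36 against -0.21 to -0.041) and xenobiotic genes (0.28 against -0.19 to -0.0069). Controls 4 and 5 were the lowest controls for both of the latter lists.

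Core clock genes and their outputs went both ways. Arntl fell, and its counter-phased targets Dbp (0.97 ± 0.27) and Hlf (0.69 ± 0.15) rose. Over all genes 2 of 16 members rose and 1 fell (3 and 2 adjusted over the list alone). The list, which holds genes of both phases, did not pass (median 0.24, camera adjusted p = 0.0834). The time of day and the feeding state at collection, which are not given, could not be taken into account. In replicates 4 and 5 alone Arntl differed by -1.59, Dbp by 0.83 and Hlf by 0.39.

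The other lists did not pass the camera test. Fatty acid oxidation and PPAR-alpha target genes had 1 member higher, Hadh (0.46 ± 0.080, 0.080 after quantile normalization), and 2 of 29 lower, Vnn1 (-0.40 ± 0.10) and Etfdh (-0.50 ± 0.14, -0.021 in replicates 4 and 5 alone). The list median was 0.066 (adjusted p = 0.854). Genes of amino acid breakdown and of arginine and creatine synthesis went both ways, 3 higher and 3 lower of 31, with Cbs (0.93 ± 0.21) higher and the arginase Arg2 (-1.22 ± 0.28) and Ddc (-0.62 ± 0.13) lower (median 0.012, adjusted p = 0.852). Of the tricarboxylic acid cycle 2 of 18 genes rose (median 0.066, 0.0755), citrate synthase among them (Cs, 0.57 ± 0.12), whose 2 other probe sets moved the other way without passing. Sirtuin and NAD genes had 2 higher and 1 lower of 21 (median 0.058, 0.609), the lower one being Sirt1 (-0.53 ± 0.12). Vitamin D, calcium and phosphate genes had 3 of 22 higher (median 0.19, 0.0696), including the phosphate transporter Slc34a1 (0.39 ± 0.081, 0.10 after quantile normalization). Autophagy and lysosome genes had 2 higher and 2 lower of 27 (median 0.0093, 0.852), with Atg5 lower (-0.70 ± 0.14). Endoplasmic reticulum stress genes had Calr higher (0.44 ± 0.094) and Dnajb9 lower (-0.54 ± 0.12) of 20 (median -0.067, 0.865).

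For the remaining lists the median and the camera adjusted p were -0.0081 and 0.854 for the proteasome (2 of 31 higher) and -0.11 and 0.467 for heat shock proteins (1 of 20 lower). They were 0.069 and 0.396 for interferon-stimulated genes (0 of 25 past the threshold) and -0.36 and 0.207 for senescence genes (1 higher and 1 lower of 10). For proliferation genes they were -0.019 and 0.852 (1 of 11 higher) and for insulin and IGF signalling -0.052 and 0.852 (2 of 22 higher). For female-biased kidney genes they were -0.029 and 0.813 (0 of 6 past the threshold) and for renin-angiotensin and salt transport genes 0.063 and 0.107 (3 of 20 higher). The female-biased transporter Slc22a7 differed by -1.67 ± 0.65 without passing (adjusted p = 0.127), and by -2.84 in replicates 4 and 5 alone. The median, the mean and the camera direction of the fatty acid oxidation, proteasome, proliferation, insulin, autophagy, thick limb and amino acid lists differed in sign. In all, 21 of 44 lists passed with camera's preset correlation, 11 higher and 10 lower. With an estimated correlation 0 passed (2 at an unadjusted p under 0.05). With fry 2 passed, the respiratory chain and the proximal tubule, both at adjusted p = 0.0289 (16 unadjusted). With the exact permutation test of array means 0 passed (15 unadjusted). Some lists called by camera were not under 0.05 in this test even unadjusted. Their exact permutation p was 0.111 for cholesterol synthesis, 0.0635 for fatty acid synthesis and 0.0873 for gluconeogenesis. It was 0.0635 for glucocorticoid and FoxO, 0.127 for NRF2, 0.0873 for androgen-dependent and 0.143 for transporter genes.

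Of the 23 lists that did not pass, 13 passed in at least 1 alternative. The tricarboxylic acid cycle list passed in 9 of 25, among them the 3' to 5' covariate (median 0.14, adjusted p = 4.86e-05) and replicates 4 and 5 alone (0.24, 7.81e-07, range 7.81e-07 to 0.392). Neutrophil markers passed in 6 of 24, with -0.76 in replicates 4 and 5 alone (0.0145, range 0.0126 to 0.358). The senescence list passed in those arrays (median -0.63, adjusted p = 0.00404, range 0.00349 to 0.833) and with quantile normalization on them (-0.67, 0.00349). Controls 4 and 5 had the highest senescence list means of the controls (0.25 and 0.35 against -0.27 to -0.11) and the lowest of the tricarboxylic acid cycle list (-0.079 and -0.10 against 0.043 to 0.068). Control replicate 5 had the highest neutrophil list mean (0.96). Also past the threshold in replicates 4 and 5 alone were the amino acid (0.19), sirtuin and NAD (0.13) and proteasome lists (0.12), with control replicate 4 the lowest control for the first 2 (-0.21 and -0.085) and control replicate 5 for the last (-0.16). With 1 array left out, the clock list passed without control replicate 2 or 4 or calorie-restricted replicate 2 (medians 0.28, 0.31 and 0.29). The vitamin D, calcium and phosphate list passed without control replicate 2 (0.21) or calorie-restricted replicate 3 (0.18), and the interferon list without the latter (0.19). The tricarboxylic acid cycle list passed without control replicate 1 (0.11), control replicate 2 (0.063) or calorie-restricted replicate 3 (0.076). The neutrophil list passed without control replicate 1 (-0.45) or calorie-restricted replicate 2 (-0.68). Among lists that passed over all arrays, the median of the matrix and NRF2 lists was -0.17 and 0.10 without control replicate 5, and those of the fatty acid synthesis and hypoxia lists 0.13 and 0.082 without calorie-restricted replicate 1. Those of the B cell and gluconeogenesis lists were -0.66 and 0.16 without calorie-restricted replicate 2, and that of the adipocyte list -0.45 without calorie-restricted replicate 5.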

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

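The comparison of replicates 1 to 3 with replicates 4 and 5 was chosen after the result was seen, while the splits of the arrays and the random lists of like brightness were planned. The number of probe sets that passed, 1371, was reached by 1 of 100 drawn splits of the 10 arrays into 5 and 5, the real one. The highest other count was 12, so a random split is unlikely to give such a count. For genes the real split was also the only 1 of 100, with 1050 against at most 11. The 3' to 5' ratio also differs across the real split, so the splits do not tell diet from RNA quality. For the number of gene lists, 12 of 100 splits reached the real 21 (highest other 29), and for lists of immune genes, immune cells and other tissue 27 of 100 reached the real 4 (highest other 7), so chance cannot be excluded for these 2 counts.

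An RNA quality difference between arrays is a candidate explanation for part of the differences seen in replicates 1 to 3. Of 1809 probe sets with an unadjusted p under 0.001 there, where the 3' to 5' ratio differed by 1.12 between the diets, 53.6% had the same sign in replicates 4 and 5, where it differed by -0.12. If the sizes measured in replicates 1 to 3 were the true ones in both, 99.99% would have the same sign. Choosing probe sets by their p inflates those sizes, so equal effects would give a lower share, which was not worked out. Of 313 probe sets chosen in replicates 4 and 5, 73.5% had the same sign in replicates 1 to 3. Neither set is the 1371 that passed over all arrays: of those, 1357 of 1366 had the same direction in replicates 4 and 5 alone, at a median of 0.728 of their size, and 1362 of 1362 with calorie-restricted replicates 4 and 5 against all controls, but they were chosen on data that include these arrays. RNA quality, diet and other differences between the mice all stay open for the count.

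The rise of bright transcripts could come from a brightness-dependent shift that the authors' scaling left. The respiratory chain median, 0.18, lay at the 11.7 percentile of 10000 random lists of like brightness, whose median was 0.22, which goes with such a shift, while with quantile normalization on replicates 4 and 5 the median was 0.10 and the list still passed. The proximal tubule median, 0.38, lay above all 10000 lists drawn for it (percentile 100, random median 0.20), so these markers rose more than other genes of like brightness. Genes of a random list were drawn singly, so the percentile does not show how often genes that move together would reach this median. A shift together with such movement is not excluded. Ribosomal protein genes, at 0.13, lay below most of theirs (percentile 0.07, random median 0.25), and a fall of these genes under a shift cannot be told apart from a weaker shift of them, since no value fixes the size of the shift for single genes. A change of proximal tubule cells with the diet stays open and was not tested.

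In 22 of 286 groups of 5 arrays 1 array stood far from the other 4, where chance gives about 1 in 20, or 14.3. Control replicate 1 stood apart for Cpe at a signal of 4217 (others 2452 to 2936), Acss2 at 6585 (3441 to 4284) and Slc22a2 at 5856 (2820.2 to 3299). It was below the others for Rpl38 at 25183 (28451 to 29703), Umod at 22090.2 (26146 to 27424) and Arg2 at 350.2 (914 to 1109). Control replicate 5 stood apart for Iglv1 at 3382 (1139 to 1571), Pou2af1 at 806 (286 to 435), Loxl1 at 2131 (1517 to 1582) and C3ar1 at 401 (250.5 to 281), and control replicate 4 for Ccl2 at 405 (156 to 209). Among calorie-restricted arrays replicate 1 stood apart for Ccl2 at 63.9 (104 to 115), replicate 2 for Sirt1 at 436 (514 to 539) and replicate 3 for Clca3a1 at 610.1 (742 to 785) and Dbp at 9113 (5539 to 6554). Replicate 4 stood apart for Hspb7 at 130.4 (179 to 188) and replicate 5 for Mrc1 at 531 (255 to 315). Of the list means, relative to the control mean, control replicate 1 stood apart for the androgen-dependent list at 1.05 (others -0.51 to -0.060) and the ribosomal list at -0.11. Control replicate 4 stood apart for the proximal tubule list at -0.20, control replicate 5 for the proteasome list at -0.16 and calorie-restricted replicate 1 for the autophagy and lysosome list at -0.063.

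In the control probe sets that take no part in the comparison, the mean log2 signal of the spiked-in bacterial transcripts was higher in calorie-restricted kidney by 0.69 (11.57 to 12.26), that of the B1 repeat by 0.70 (12.52 to 13.22) and that of the B2 repeat by 0.36 (12.27 to 12.63), each with an exact permutation p of 0.0159. In replicates 1 to 3 the B1 means were 12.42 in control and 13.54 in calorie-restricted kidney and the B2 means 12.23 and 12.79. In replicates 4 and 5 they were 12.68 and 12.74 for B1, 12.32 and 12.40 for B2, and 11.54 and 11.92 for the spiked-in transcripts.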

How the results depend on the processing

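The settings with the 3' to 5' covariate, with replicates 4 and 5, and the exact test of array means were chosen after seeing the data. The 1371 probe sets and 1050 genes became 287 and 228 without a filter on dim probe sets, 763 and 625 with quantile normalization, 243 and 196 with eBayes without trend, 2292 and 1779 with array weights, 3246 and 2480 at an adjusted p under 0.10 and 704 and 557 with a fold of at least 1.5. They became 127 and 108 with the replicate block (118 probe sets shared), whose numbers show no pairing of the mice: the deviations of arrays with the same number correlated at -0.14 to -0.087. They became 9 and 8 with the 3' to 5' covariate, 5 and 5 with quantile normalization and the covariate, 2 and 2 with calorie-restricted replicates 4 and 5 against all controls, 207 and 152 with replicates 4 and 5 of each group only, and 173 and 129 with quantile normalization on those. At an unadjusted p under 0.05 limma gave 2984, 2423 and 3584 probe sets with the covariate, with those 2 calorie-restricted arrays and with replicates 4 and 5 only, against 5885. With the covariate all 1371 kept their direction, at a median of 0.741 of their size and 1.24 of their standard error, and 6 of them still passed. They were chosen on these same arrays, so the kept direction was largely set in advance. Fewer arrays or an added term widen the error in these settings, and beyond that the cause was not tested. The mean of a gene's probe sets gave 575 genes. Leaving out 1 array gave 125 (without control replicate 2) to 2485 (without calorie-restricted replicate 5) probe sets and 97 to 1907 genes. Median centring gave 1534 probe sets, 986 of them higher. The 21 lists became 0 with an estimated correlation, 2 with fry and 0 with the exact test of array means, and the 4 lists of immune genes, immune cells and other tissue became 0, 0 and 0; camera gave 16 to 27 lists in the other settings. The median of the fatty acid oxidation list turned to -0.10 with quantile normalization and the covariate and -0.13 with quantile normalization on replicates 4 and 5, and that of the insulin list to -0.13 on the latter. The ribosomal list turned to -0.070 with quantile normalization, -0.065 with the covariate beside it and -0.072 on replicates 4 and 5, and Rpl38 to -0.017, -0.042 and -0.050. The hypoxia list turned to -0.039 and -0.073 in the last 2 of these settings. Quantile normalization levels the brightness trend by construction. Of 2432 values of named genes 1406 kept direction and side of the threshold, 1003 kept the direction but no longer passed, 16 newly passed, 4 changed sign without passing in either setting and 3 changed direction with a call. Of 1230 list values, here with the estimated correlation, fry and the exact test included, these numbers were 1011, 108, 35, 68 and 8 by the direction of the list test. The hypoxia list in replicates 4 and 5 counts among the 108, though its median turned to -0.044. The RNA quality difference was 0.18 for Pcx alone (exact p = 0.389) and 0.49 to 0.75 without single arrays. Signals near the background limit what can be called for dim transcripts.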

Other observations

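The tests of RNA quality, dilution and T cell markers here were chosen after the results were seen, as were the genes named in the first 3 paragraphs except Alb, Fgg, Nat8f1, Ak4 and Gem. An Ighm probe set, for the heavy chain of IgM, fell from 7740.4 ± 3295 to 1298 ± 1295 signal units (SD, n = 5), a log2 difference of -3.20 ± 0.60, and of -4.99 with the 3' to 5' covariate. The brightest Ighm probe set, which gives the gene's value by the rule used here, went from 20825 ± 4579 to 11579.5 ± 6632. It differed by -0.99 without passing (limma adjusted p = 0.0579), and calorie-restricted replicate 3, at 22312, lay above 3 of 5 controls. An Igk probe set, too dim on average for the comparison, had signals of 328 to 1659 in control and 7.28 to 25.2 in calorie-restricted kidney. The Igk probe set and the dimmer Ighm probe set were the ones that passed with calorie-restricted replicates 4 and 5 against all controls, the latter at -4.78. The Igk signals in calorie-restricted kidney lie below the array medians of 115 to 136, where background is not told from signal, so no size is given for it. Probe sets of this family can bind several immunoglobulin transcripts. One hypothesis is that calorie-restricted kidney may hold fewer lymphocytes of all kinds. T cell markers had a median of 0.041 against -1.0 for the B and plasma cell list, and the per-array difference separated the diets (exact permutation p = 0.00794, the smallest 5 against 5 can give). The T cell markers had a median log2 signal of 7.50, among the dimmest tested, against 8.58 for the B and plasma cell list, so the test leaves the hypothesis open. The rule that markers this dim decide nothing was added after that value was seen, and without it the test would have counted against the hypothesis.

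Plasma protein genes that liver cells express moved apart. Alb rose from 523 ± 193 to 1704 ± 1206 signal units (SD, n = 5), a log2 difference of 1.53 ± 0.36, while the fibrinogen chain Fgg fell from 3008 ± 944 to 1347 ± 189.8, a difference of -1.10 ± 0.20. The fibrinogen chain Fga differed by -0.71 ± 0.21 (limma adjusted p = 0.0549) and by -1.31 ± 0.16 with the 3' to 5' covariate (0.0169). It also passed in replicates 4 and 5 alone (-1.49) and without control replicate 1 (-0.84). Also past the threshold with that covariate were Nat8f1, 2 probe sets of Ak4, Ighm, Gem, F2r (-0.80), the bile acid transporter subunit Slc51a (1.45) and the matrix protein Matn2 (-1.45).

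The androgen-dependent or male-biased genes Slco1a1 and Cyp2j13 stood far above the other controls in control replicate 1. Slco1a1 had a signal of 1662 in it against 77.1 to 116 in the other controls and 249.5 to 1292 in calorie-restricted kidney, and Cyp2j13 4238 against 392 to 689 and 1376 to 2926. Over all arrays they differed by 1.63 and 1.32 without passing (limma adjusted p = 0.164 and 0.0996). Without control replicate 1 they differed by 2.46 and 1.89 and passed, but that array and these genes were picked for their values, so that is not a test. The Slco1a1 signals of the other controls each lay below the median signal of their array, so the sizes given for this gene are uncertain.

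The fall of macrophage, complement, matrix and tubule injury genes, with a median of -0.46 over 80 genes, was set against 3 technical explanations. These 4 lists were singled out as lower on these same arrays. All 3 comparisons reuse those values, so part of their outcome was set in advance and none is an independent test. A brightness-dependent shift would leave the median within that of random lists of like brightness; it lay below all of them, at percentile 0 of 10000, where the random median was 0.0054. In replicates 4 and 5 the median was -0.60, with 77 of 80 genes lower, which goes against RNA quality as the whole of the fall. These arrays took part in singling out the lists. Of the controls, replicates 4 and 5 had the highest means of these genes (0.18 and 0.36) and also the highest 3' to 5' ratios. With calorie-restricted replicates 4 and 5 against all controls the median was -0.31. Dilution by proximal tubule RNA as the whole of it would lower other segments alike, and their markers had a median of 0.041 over 35 genes (exact permutation p = 0.00794 for the difference, the smallest 5 against 5 can give), while podocyte, stromal and endothelial markers, at -0.32, -0.25 and -0.11, leave dilution open as a part. A lower content of these cells or transcripts under calorie restriction is a hypothesis that these data leave open.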
